A study of Tetranychus truncatus with 6 samples.

How the data were processed

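The series holds 6 RNA-seq libraries of whole adult Tetranychus truncatus, a spider mite reared in the laboratory, 3 after abamectin at the concentration lethal to 30% and 3 after 27.5% acetone in water. Per the labels' protocols, total RNA was extracted with Trizol, 3 μg per sample entered library preparation, and Illumina protocols were used. The submitters' processing notes name Bowtie 1.1.1. The assembler, the counting program and any filter are not given in the sources used here. The feature names have the form of assembly component numbers, so the features are called unigenes. No genome, transcript sequence or gene name table was used, and gene names and genomic positions are not reported. For the same reason the 28 gene lists and their set tests, planned before the data were examined, were not run.

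The authors deposited 1 table per library with a read count and an FPKM value (fragments per kilobase of unigene per 1000000 mapped fragments) for each unigene, per the file headers. The deposited counts are whole numbers. In each library 1 to 4 unigenes had an FPKM above 0 beside a count of 0, and 0 unigenes had the reverse, so the counts appear to be rounded estimates; how reads shared between related unigenes were divided is not given. Each table went on after its last unigene with 1 broken identifier followed by 2586 to 2670 rows that repeat earlier rows, all with identical values. These repeats were dropped, which left 55272 unigenes per library. They held at most 0.00487% of a library's counts.

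Groups and replicate numbers came from the sample titles, which number the libraries 1 to 6 through both groups. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical in part. The main test was edgeR 4.0.16 (R 4.3.3) on the counts of all 6 libraries: filterByExpr by group, trimmed mean of M-values (TMM) scaling, quasi-likelihood fit with treatment as the only term, two-sided test and Benjamini-Hochberg adjustment, with a threshold of 0.05. The filter kept 10204 unigenes, and between 0.114% and 0.254% of a library's counts lay outside them. TMM factors ran from 0.883 to 1.09. The biological coefficient of variation was 22.6%. Standard errors of log2 fold changes were derived from the F statistic. The named unigenes were, by a rule fixed before the data were examined, the 2 with the largest absolute log2 fold change in each direction among those past the threshold with a mean of at least 1 CPM and with every abamectin library on the same side of every control library.

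The test was tried on simulated counts with the means, library sizes and dispersions of the 10204 unigenes. It recovered 45.5% of 200 unigenes changed 2-fold, with 3.19% false calls, and 88.0% of 200 changed 4-fold, with 6.38% false calls. The changed unigenes were drawn only from those above a minimum expected count. Each unigene varied independently, without shifts shared by a whole library, so these rates may not hold for the data.

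An effective length was derived for each unigene as the count divided by FPKM and by the library total, as the median over libraries. Ratios between libraries for unigenes over 3000 nt lay between 0.991 and 1.00. Because FPKM has 2 decimals, the lengths of weakly expressed unigenes are approximate. Thinning drew each library once, without replacement, down to 18109230 counts. Shares were compared by exact permutation tests, and lengths by 100000 permutations, or 20000 for each alternative (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Floors for a count of 0 are 3 counts over the 3 libraries of a group, and floors and intervals cover counting error only.

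Alternatives fixed before the data were examined were DESeq2 size factors within edgeR, library size alone, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust shrinkage, and leaving out each library. Added after seeing the data were leaving out the most abundant assembly component, limma on log2(FPKM + 1) for unigenes with an FPKM of at least 1 in 3 libraries, counting the repeated rows again, and equal depth. The sets of unigenes present in one group, their minimum of 10 counts, the abundance and length classes and the length comparison were also chosen after seeing the data.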

Results

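The response of the spider mite Tetranychus truncatus to abamectin was measured by RNA sequencing of whole adult bodies. Abamectin is a macrocyclic lactone acaricide that opens glutamate-gated chloride channels of nerve and muscle. The treated group (3 libraries, replicates 1 to 3) received abamectin at the concentration expected to kill 30% of the mites. The control group (3 libraries, replicates 4 to 6) received 27.5% acetone in water. No acetone percentage is recorded for the abamectin libraries, so a difference in solvent cannot be told apart from abamectin. Expression was available for 55272 unigenes, the transcripts of an assembly, which carry component numbers and no gene names. The 28 gene lists fixed beforehand therefore could not be matched to unigenes and were not tested. Detoxification enzymes, target channels, cuticle, heat shock, egg and symbiont genes were among them. The unigenes are grouped below by their presence, abundance and length.

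The abamectin libraries held 18954776, 39982117 and 38331843 counts (replicates 1, 2 and 3) and the control libraries 20812552, 18109230 and 27849837 counts (replicates 4, 5 and 6), a 2.21-fold range. Between 8708 and 9042 unigenes per library exceeded 1 CPM (counts per 1000000 counts of the library). Of all unigenes, 12421 had a count in every library and 6471 had none in any. Abamectin replicate 2 stood apart in the number of unigenes with at least 1 count, 33241 against 20001 to 23441 in the other 5 libraries.

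A single unigene, c30159.graph_c0 (effective length 9158 nt), took between 18.0% and 32.7% of all counts in each library. It is named here because of its abundance, after its values were seen. Its share was 21.7% ± 4.30 (SD, n = 3) in the abamectin group and 28.5% ± 4.50 (SD, n = 3) in the control group, which did not separate the groups (two-sided exact permutation test, p = 0.2, where 0.1 is the smallest value that 3 against 3 libraries allow). The next 2 most abundant unigenes belonged to the same assembly component, with effective lengths of 5367 and 7820 nt. Together they took 6.95% ± 0.464 (SD, n = 3) of the counts after abamectin and 3.39% ± 0.935 (SD, n = 3) in the controls, and each abamectin library lay above each control library (two-sided exact permutation test, p = 0.1, the smallest possible). In edgeR's quasi-likelihood test their log2 fold changes were 1.08 ± 0.29 (SE) and 0.93 ± 0.31 (SE), and neither passed the threshold (adjusted p = 0.0773 and 0.108). The Wilson 95% intervals of these shares were at most 0.0432 percentage points wide and cover counting error only.

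Treated and control libraries separated along the first principal component of log2 CPM, which held 48.5% of the variance. The 3 abamectin libraries had scores from 25.0 to 38.1. Controls 4 and 5 had scores of -43.5 and -39.1, whereas control 6 lay at -11.6, between them and the abamectin libraries. The second component (25.8% of the variance) ran between control 5 (31.5) and control 6 (-48.6). Over all tested unigenes, control 6 correlated less with control 5 (Pearson r = 0.959) than with the abamectin libraries (0.961 to 0.971). With control 4 it correlated more (0.975). Among the 5990 tested unigenes with a mean of at least 10 CPM, 631 differed by 2-fold or more between controls 5 and 6, 237 between controls 4 and 6 and 76 between controls 4 and 5. The corresponding numbers between pairs of abamectin libraries were 26 to 82. The chi-square statistic of the counts was at least 44.0 times its degrees of freedom for each pair of libraries. This covers counting error only, and separate preparations of 1 sample would also exceed it. The 6 libraries were kept as separate samples, as labelled.

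**Figure D1:**
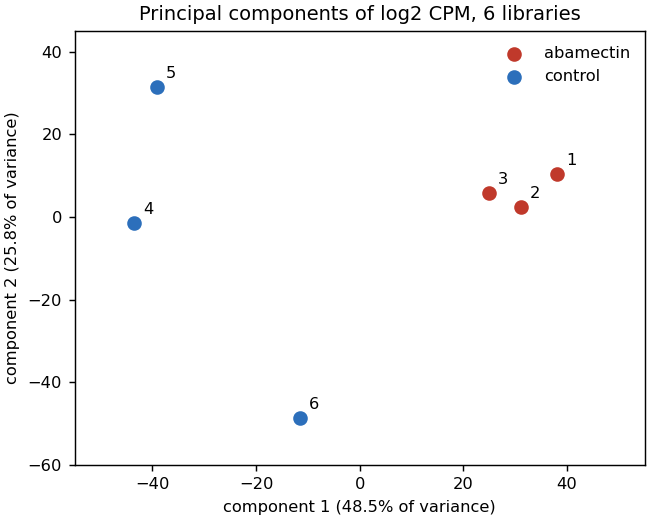
Scores of the 6 libraries on the first (x axis, 48.5% of variance) and second (y axis, 25.8%) principal components of log2 CPM over the tested unigenes; each point is 1 library, numbered by replicate. The abamectin libraries lie together between 25.0 and 38.1 on the first component, while the controls spread from -43.5 to -11.6.

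The comparison of abamectin with control asks which transcripts differ between mites given abamectin and the acetone controls. Of 10204 unigenes tested, 134 were higher and 179 were lower after abamectin. Before adjustment, 2820 had p under 0.05 in edgeR's quasi-likelihood test, so the calls need not hold the full extent of the difference. Among the calls, the 158 lower unigenes with counts in both groups fell by a median of 2.32-fold, and the 103 higher ones with counts in both groups rose by a median of 1.78-fold. Lower calls also had the larger median SE (0.222 against 0.149 log2 units). A unigene with a larger SE needs a larger fold change to be called, so the threshold alone could give such a difference in fold. The SE was derived from the fold change itself and taken over calls only. It therefore cannot decide whether lower calls changed more strongly. The median log2 fold change over all tested unigenes was -0.015. With unigenes at 0 in a whole group set at their lower bound, the median changes were 2.83-fold for the lower and 1.96-fold for the higher calls. Of the changed unigenes, 180 differed by at least 2-fold, 64 of them higher and 116 lower. Fitted changes of at least 4-fold were found in 63 lower and 34 higher unigenes, of which 42 and 3 had counts in both groups. Calls are those with an adjusted p under 0.05 in edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment.

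These counts depended strongly on single libraries. Without control 4, 5 unigenes passed; without abamectin 2, 13; without abamectin 3, 48; and without abamectin 1, 55. Without control 5 or control 6, which lie at opposite ends of the second component, 1729 and 1722 passed, including 313 and 309 of the 313. The balance of directions differed between these: 1105 higher and 624 lower (36.1% lower) without control 5, and 565 higher and 1157 lower (67.2% lower) without control 6. DESeq2 called 1415 unigenes, and limma on the deposited FPKM called 102. Scaling by library size alone gave 206 higher and 182 lower unigenes (46.9% lower, against 57.2% in the main test). Of the 313 changed unigenes, 0 had the opposite sign under any of the 17 alternatives in which they could be fitted. In all 313, every abamectin library lay on the same side of every control library. That left little room for a change of sign, so the constant sign does not measure stability.

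**Figure D2:**
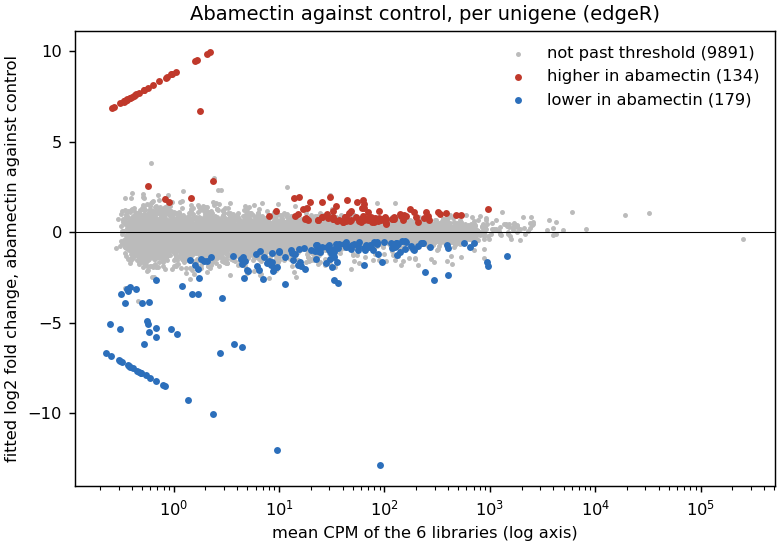
Fitted log2 fold change of abamectin against control (y axis) against mean CPM over the 6 libraries (x axis, log scale) for each of the 10204 tested unigenes; red points are the 134 higher, blue points the 179 lower and grey points those that did not pass. The 2 straight bands of points at the far left are unigenes with a count of 0 in a whole group, whose fitted fold depends on the prior count.

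A distinct group of transcripts was present in one treatment and missing from the other. In all, 43 unigenes had at least 10 counts in each abamectin library and 0 counts in each control library, and 20 had at least 10 counts in each control library and 0 in each abamectin library. Of these, 31 and 19 were among the tested unigenes. They were weakly expressed: the median count per library was 23 in the first set and 22 in the second. Summed over its members, the first set reached 48.6 ± 10.6 CPM (SD, n = 3) after abamectin, with 60.5, 40.2 and 45.1 CPM in replicates 1, 2 and 3. The second set reached 42.8 ± 3.96 CPM (SD, n = 3) in the controls, of which c30517.graph_c0 alone gave a mean of 19.2 CPM. A count of 0 over the 3 control libraries allows up to 0.0449 CPM, and over the 3 abamectin libraries up to 0.0308 CPM. The minimum of 10 counts was chosen after the data were seen; with at least 5 counts the sets held 95 and 40 unigenes, with at least 20 counts 17 and 7, and at equal depth 24 and 20. With at least 30 counts over the group and 1 in each library they held 73 and 29, and with no minimum per library 352 and 30, of which 279 and 1 lacked a count in at least 1 library of the group. Without abamectin 3, the first set held 80.

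The unigenes named by the fixed rule, those with the largest fitted change in each direction, included 3 members of these sets and c14609.graph_c0, which had 2 counts in abamectin 1. The unigene c30315.graph_c0 (effective length 1700 nt) had 113, 140 and 146 counts in the abamectin libraries, or 4.42 ± 1.34 CPM (SD, n = 3), and 0 in each control. It was at least 91.3-fold higher after abamectin, against a floor of 3 counts over the control group (adjusted p = 0.00871, edgeR). The unigene c27859.graph_c0 (effective length 1902 nt) had 103, 128 and 140 counts, or 4.10 ± 1.18 CPM (SD, n = 3), and 0 in each control, at least 84.9-fold higher (adjusted p = 0.00871, edgeR). Both missed the threshold without control 4 (adjusted p = 0.0521, edgeR).

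On the lower side, c14609.graph_c0 (effective length 8577 nt) had 4498, 3871 and 3276 counts in controls 4, 5 and 6, or 183 ± 56.2 CPM (SD, n = 3). The abamectin libraries held 2, 0 and 0 counts. The ratio of pooled CPM was 8482, with an exact 95% counting interval of 2347 to 70046 (adjusted p = 0.000317, edgeR). It rests on the 2 counts of abamectin 1; without that library the unigene was at least 4553-fold lower, against a floor of 3 counts over the 2 remaining libraries. The unigene c30517.graph_c0 (effective length 9302 nt) had 424, 290 and 588 counts in the controls, or 19.2 ± 2.76 CPM (SD, n = 3), and 0 in each abamectin library, at least 632-fold lower (adjusted p = 0.000446, edgeR). Both passed the threshold in each of 17 alternatives, with adjusted p of at most 0.0112 and 0.017.

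**Figure D3:**
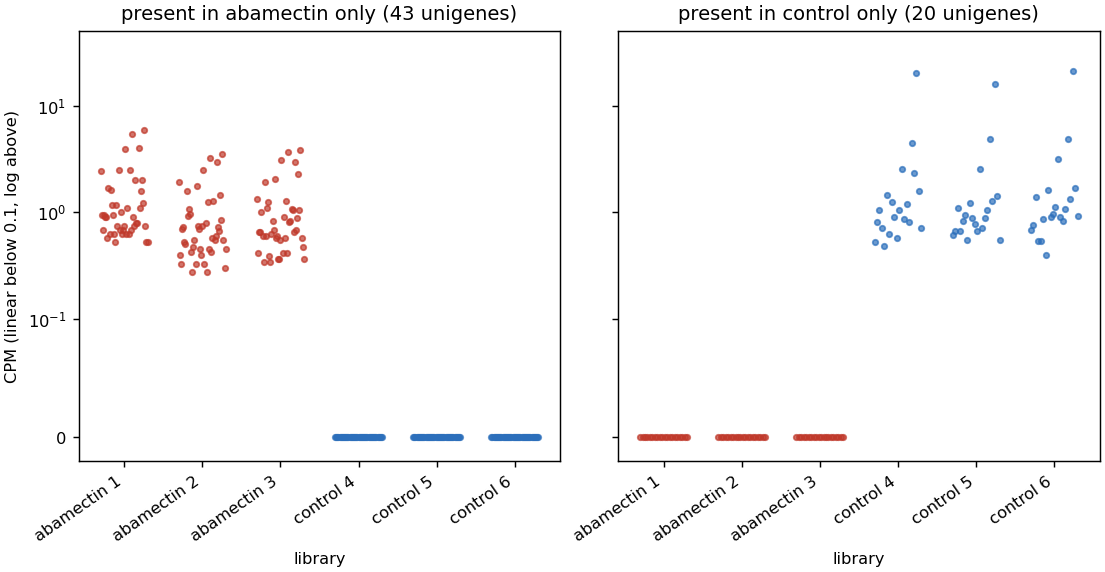
CPM (y axis, linear below 0.1 and logarithmic above) of the 43 unigenes present in each abamectin library and absent from the controls (left) and of the 20 with the opposite pattern (right), in each of the 6 libraries (x axis); each point is 1 unigene, spread sideways for visibility, with abamectin in red and control in blue. Both sets sit at 0 in every library of the other group because they were chosen that way.

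Changed unigenes were found at all levels of abundance. Of 1373 tested unigenes with a mean under 1 CPM, 29 rose and 36 fell. Most of these 29 were among the 31 higher calls with no count in any control. For higher calls this class therefore largely repeats the set present after abamectin only. Of 2841 between 1 and 10 CPM, 10 rose and 42 fell. Of 4295 between 10 and 100 CPM, 68 rose and 68 fell, and of 1695 above 100 CPM, 27 rose and 33 fell.

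Unigenes that rose were longer than those that fell. The median effective length was 2262 nt for the higher and 1445 nt for the lower calls, against 1884 nt for all tested unigenes (permutation test of the mean log2 length, two-sided, p = 0.00018 over 100000 permutations; unigenes are not independent replicates). Among 2691 tested unigenes of 3000 nt or more, 46 rose and 17 fell; among 3563 between 1500 and 3000 nt, 48 and 66; among 3223 between 500 and 1500 nt, 30 and 82; and among 727 under 500 nt, 10 and 14, so the shortest class did not follow the trend. The shift was also measured over all tested unigenes of these lengths, with the calls included. Relative to the mean of the 6 libraries, unigenes of 3000 nt or more exceeded those under 1500 nt by 0.12 ± 0.04 log2 units (SD, n = 3) in the abamectin libraries and by -0.12 ± 0.14 (SD, n = 3) in the controls (two-sided exact permutation test, p = 0.1, the smallest possible). The control values were -0.27, 0.00 and -0.11 for replicates 4, 5 and 6. The group means mirror each other because the values are centred on the mean of the 6 libraries. The length difference of the calls (0.47 log2 units) was 0.91 with scaling by library size alone, 0.70 with DESeq2 and 0.21 with no filter, and did not pass at equal depth (0.18 log2 units, permutation p = 0.266) or with a filter of 5 CPM (0.22, permutation p = 0.199). On FPKM, with 102 calls, it was 0.56 (permutation p = 0.0808). It did not pass without abamectin 1 (0.61 log2 units, permutation p = 0.0574) or without abamectin 3 (0.15, permutation p = 0.652), and without abamectin 2 it was -0.18 (permutation p = 0.841).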

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

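The main counts were 313 changed, 134 higher, 179 lower and 180 changed over 2-fold, and in each setting below these are given in this order. DESeq2's Wald test gave 1415, 642, 773 and 455, among them all 313, and no filter gave 1841, 1178, 663 and 963. The filter of 5 CPM, which tested 6855 unigenes, gave 136, 37, 99 and 57, and limma on FPKM, added after seeing the data, gave 102, 49, 53 and 84. Scaling by library size alone gave 206 higher unigenes and equal depth gave 80; their other counts stayed within 1.5 times. Leaving out 1 library gave 5 to 1729 changed, 2 to 1105 higher, 3 to 1157 lower and 5 to 788 over 2-fold, lowest without control 4. With DESeq2 size factors, limma-voom, robust shrinkage, the repeated rows or no dominant component, each count stayed within 1.5 times. Without the filter the median log2 fold change of all unigenes moved by 0.67, and under the other settings by less than 0.1. The cause of these differences was not tested.

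The 4 named unigenes kept their direction in each alternative that tested them. The rule that named them required every abamectin library on the same side of every control library, which left little room for a reversal. Presence in abamectin alone gave 95 unigenes at 5 counts, 17 at 20 counts, 352 at 30 counts over the group, 73 at 30 counts over the group and 1 in each library, 24 at equal depth and 43 to 80 with 1 library left out; presence in control alone gave 40, 7, 30, 29, 20 and 21 to 25. The length difference between higher and lower calls (0.47 log2 units) turned to -0.18 without abamectin 2 and lay between -0.18 and 0.92 in 5 of the 6 settings that leave out 1 library (without control 4 the calls were too few); it was 0.91 with scaling by library size alone, 0.70 with DESeq2 and 0.21 with no filter. No paired analysis was possible because the groups share no replicate numbers. Apart from limma on FPKM, the alternatives for normalized values were not run because the tables held counts. The test on simulated counts, with unigenes varied independently and changes placed only above a minimum expected count, found 45.5% of 2-fold changes.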

Other observations

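The tests below were chosen after the values they measure had been seen, except the test of depth for control 6, which was set before.

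The unigenes present in the controls only kept a nearly constant ratio to each other across the control libraries. For the 20 with at least 10 counts in each control, the chi-square statistic of their counts was 0.963 times its degrees of freedom, against a median of 3.92 over 1000 sets of other tested unigenes of like abundance with the same minimum, and 0% of those sets were as low. A minimum in each library lowers this spread by itself. Chosen instead by at least 30 counts over the group and 1 in each library, 29 unigenes gave 1.07 against a median of 4.29, and again 0% of sets were as low. For the 43 unigenes found after abamectin the value was 1.07 against a median of 2.29 (0.1% of sets as low), but by at least 30 counts over the group and 1 in each library, 73 unigenes gave 3.01 against a median of 3.20, and 38.2% of sets were as low. With no minimum per library at all the abamectin set is of another kind: 279 of its 352 unigenes had no count in at least 1 abamectin library, and 77 had counts in 1 only. These 352 gave 19.6 against a median of 3.85, and 100% of sets were as low. Chosen in the same way, the 30 control unigenes gave 1.45 against a median of 4.46, and 0% of sets were as low. A split by depth gave 0 unigenes at 0 in the 3 shallowest libraries and at 10 or more counts in each of the 3 deepest. Library totals span only a 2.21-fold range, so that result was near certain and cannot decide on an effect of depth. At equal depth the abamectin set fell from 43 to 24 unigenes and the control set stayed at 20. The size of the abamectin set thus depends on depth. For the control set a candidate explanation is 1 source of RNA, such as another organism or a subset of the mites carrying different alleles. A set of transcripts with little regulation would look alike. The set leaves out c14609.graph_c0, which had 2 counts in abamectin 1. Its counts in controls 4, 5 and 6 were 4498, 3871 and 3276, lowest in the deepest control. There the sum of the set was highest (44.4, 38.3 and 45.7 CPM in the same order). This unigene did not keep the ratio, so the explanation is limited to the set. For the abamectin set a single source cannot be told apart from others, because the result depends on how the set is chosen. The response to abamectin stays open, as untested. Among the 10 splits of the libraries into 3 and 3, only the real split (1 of 10) gave as many as 63, and the highest other gave 1; 10 splits are too few for a share under 0.05.

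Abamectin replicate 2 had a count for 11794 unigenes that no other library detected, 5.79 times the median of the other libraries. They held 0.0997% of its counts, with a median of 2 and a highest count of 225. At equal depth it still showed 27827 unigenes against 18535 to 20993 elsewhere, an excess over the highest other library of 2.78 times the range of the other 5, and abamectin 3, of nearly the same depth, had 3157 unigenes of its own, so depth is not the whole cause. RNA or DNA from another source at a low level remains possible and cannot be told apart from weak mite transcription without the sequences of the 11794 unigenes. No biological explanation was tested.

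Control 6 lay 40.9% of the way from controls 4 and 5 to the abamectin mean on the first principal component. Admixed abamectin RNA is argued against: the 43 unigenes with at least 10 counts in each abamectin library and none in controls 4 and 5 had 0 counts in control 6, where 1353 would be expected from pure abamectin RNA, which limits the admixture to 0.273% (upper 95% limit). At equal depth its position was 0.388 against 0.409 at full depth, so depth does not account for it either. A difference between the mites of the control samples, such as age or sex ratio, stays open as untested, since the labels do not give either.

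Of the 10 splits of the 6 libraries, 1, the real one, gave as many changed unigenes as 313 and 1 gave as many as 180 over 2-fold; the highest of the others gave 12 and 12. With 10 splits no share under 0.05 is possible.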
